A study of Homo sapiens with 9 samples.

How the data were processed

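RNA of THP-1 cells was measured on Illumina bead arrays in 3 states (fresh, frozen, replated) with 3 arrays each. Per the labels, total RNA was isolated with a QIAGEN miRNeasy kit and turned into biotinylated cRNA with an Ambion MessageAmp kit. Groups and replicate numbers were taken from the sample titles.

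The main table holds, per the file headers, non-normalized probe signal, an intensity on a linear scale, for 48803 probes on 9 arrays. Beside each signal the deposited table has a detection column headed as a p value. Per the file headers it is a detection value for each probe and array, and how the authors computed this score is not given in the sources used here. It is used here as a score equal to 1 minus the detection p, because it never falls as the signal of its own array rises (0 falls, against at least 998 for the signal of any other array), with steps set by 758 negative controls. A second deposited table, of values processed by the authors, holds intensity on a linear scale. Its sorted columns differed by at most 0.109% of the highest value, its lowest value was 1.45 and its highest 29548, its column medians lay between 5.039 and 5.064, and its rank correlation with the non-normalized signal of the same array was 1. These values are therefore background-corrected and quantile-normalized, with scale and direction known from the comparison. The software, the bead summarisation and the background method are not given in the sources used here. No column of the main table was left unused.

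Background was corrected with limma's neqc, which infers negative-control parameters from the detection p, applies normexp with an offset of 16, and quantile-normalizes log2 signal. Folds on this scale understate the change of dim probes. Probes detected (p under 0.05) on at least 3 of the 9 arrays were kept, which left 18102. A linear model over all 9 arrays with a shared spread (lmFit and eBayes, residual df 6, prior df 4.65) gave each contrast and a moderated F test, with Benjamini-Hochberg adjustment over kept probes and a call at an adjusted p under 0.05. The small number of arrays limits the precision.

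The annotation gave 27578 probes 1 gene symbol and 13 several, and did not list 21212. Symbols were updated through the Entrez gene ID (27541), the accession (12) or kept (38), using the gene table of GRCh38.p14. A gene was represented by its kept probe with the highest mean signal. Named genes had 7, 19 and 34 other kept probes in frozen against fresh, replated against fresh and replated against frozen cells. Of these 1, 9 and 17 were called in the same direction and 3, 2 and 5 lay in the opposite direction. The latter are given with their gene, and of the rest, which were not called, only some are. Where a probe was detected on no array of a state, the fold is a lower bound against the dimmest detected signal.

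The contrasts, tests, alternatives, gene lists and naming rule were fixed before the data were examined. The rule named, per contrast, the 10 largest increases and the 10 largest decreases among called genes whose arrays did not overlap, up to 4 called members of each list with called members or a called test, and CIRBP, RBM3, ACTB, GAPDH, FOS, HSPA1A, CD14 and MYC. RBM3 had no named probe, and the HSPA1A probe was detected on 0 of 9 arrays. The 30 lists covered heat shock, unfolded protein, amino acid and integrated stress, cold-inducible, p53, immediate early, NF-kB, interferon, NRF2, metallothionein, cholesterol, fatty acid, G1 and S phase, G2 and M phase, histone, glycolysis, hypoxia, oxidative phosphorylation, ribosomal protein, ribosome biogenesis, lysosome, apoptosis, monocyte and macrophage, immature myeloid, MHC class II, other cell type, snoRNA host, reference, osmotic and actin genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over 90 list and contrast pairs; 21 pairs were called, and 5 of these with an estimated correlation. At the preset correlation camera also called at least 1 pair in 87 of 99 other groupings of the 9 arrays (median 6 pairs), which keep part of the differences between states. In simulated data with independent probes it called 0 of 300 unchanged lists in each comparison, a setting that leaves out correlation between genes.

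Distances between arrays were compared by an exact permutation test over 280 regroupings. Alternatives were another offset, no background correction, median centring, the authors' values, other filters, a replicate block, only the states compared, array weights, another prior, a plain t-test, other thresholds, other list tests and each array left out. The methods were tested on simulated data with 200 of 18102 probes changed. In frozen against fresh cells 7.60% of 1.2-fold, 67.6% of 1.5-fold, 95.6% of 2-fold and 100% of 4-fold changes were recovered, with 5.45% false calls. In replated against fresh cells these were 12.8%, 73.6%, 97.6% and 100%, with 3.14% false, and in replated against frozen cells 8.80%, 72.4%, 95.2% and 100%, with 5.34% false. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9. The array annotation names no genome build for the probes, so no coordinates are given.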

Results

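THP-1 is a human monocytic leukemia line whose cells grow in suspension and resemble immature monocytes. Expression was profiled in THP-1 cells in 3 states, named fresh, frozen and replated, with 3 arrays per state and 9 arrays in all. The series title concerns RNA taken from stocks kept in liquid nitrogen, so the comparisons ask how the transcript profile of frozen cells, and of cells plated again, differed from that of fresh cells. The labels give no freezing, thawing or culture times. Replicates are biological, per the design text of the series, which does not say how they were separated. Each array carried 48803 probes for transcripts. A probe was detected when its signal lay above that of the negative controls, and between 16898 probes (fresh replicate 3) and 17679 probes (fresh replicate 2) were detected per array. The mean number detected was 17305.3 ± 391.6 in fresh, 17400.0 ± 78.0 in frozen and 17111.7 ± 159.5 in replated cells (SD, n = 3). Mean signal before normalization was 351.6 ± 13.7, 327.6 ± 32.3 and 343.4 ± 11.5 intensity units in the same order (SD, n = 3). A total of 18102 probes were tested, of which 14311 carried 1 gene symbol and stood for 10919 genes.

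The states separated more clearly than replicates of a state. The root mean square difference of normalized log2 signal between 2 arrays averaged 0.192 within fresh, 0.202 within frozen and 0.184 within replated cells (3 pairs each). It averaged 0.237 between fresh and frozen, 0.236 between fresh and replated and 0.281 between frozen and replated arrays (9 pairs each). Mean distance between states exceeded mean distance within states by 0.0585, which no other of the 280 regroupings of the 9 arrays reached (exact permutation test, one-sided, p = 0.00357, the smallest this design allows). Of the 18102 probes, 1743 differed among the states in limma's moderated F test at a Benjamini-Hochberg adjusted p under 0.05, and 5147 had an unadjusted p under 0.05. That count was 712 without replated replicate 3, 945 without replated replicate 1, 983 without frozen replicate 2, 1005 without replated replicate 2 and 1111 without frozen replicate 3.

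**Figure D1:**
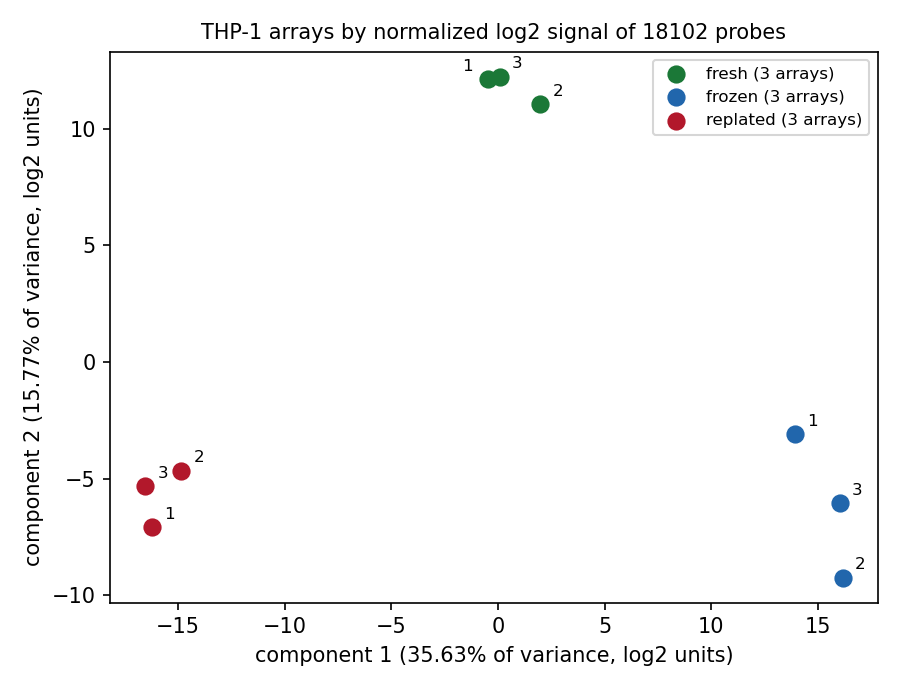
Each point is 1 array, placed by its scores in log2 units on component 1 (horizontal axis, 35.63% of the variance) and component 2 (vertical axis, 15.77%) of the normalized log2 signal of 18102 probes, with colours for states and digits for replicate numbers. Frozen arrays lay between 13.92 and 16.16 on component 1, fresh arrays between -0.49 and 1.97, and replated arrays between -16.54 and -14.86.

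In frozen cells the largest increases over fresh cells were those of immediate early genes, which are transcribed within minutes of a stimulus. DUSP1, a phosphatase that switches off MAP kinases (probe ILMN_1781285), rose 13.3-fold (log2 difference 3.73 ± 0.11, adjusted p = 2.39e-08). FOSB (probe ILMN_1751607) rose 11.1-fold (3.47 ± 0.15, adjusted p = 1.02e-06). JUN (probe ILMN_1806023) rose 10.9-fold (3.45 ± 0.091, adjusted p = 1.8e-08). Both genes encode subunits of the AP-1 transcription factor. Here and throughout, ± is the standard error of limma's log2 difference, n is 3 arrays per state, adjusted p is limma's p after the Benjamini-Hochberg adjustment over all probes tested, and the arrays of the 2 states did not overlap for any gene said to have risen or fallen unless stated. The nuclear receptor gene NR4A2 rose 3.76-fold (1.91 ± 0.091), FOS rose 3.10-fold (1.63 ± 0.10) and ATF3, a stress-induced transcription factor, rose 2.89-fold (1.53 ± 0.12). PPP1R15A, whose product restores translation after stress by directing dephosphorylation of eIF2 alpha, rose 2.36-fold (1.24 ± 0.080). EGR1 also rose (0.90 ± 0.11), chosen here after its values were seen because it led the decreases in replated cells. Of the 26 immediate early genes tested, 13 rose, 0 fell and 13 did not pass the test (20 rose when adjusted over the list alone). Their median log2 difference was 0.54, and limma's camera test put the list above other genes with an adjusted p of 1.81e-25, or adjusted p = 0.0433 with an estimated correlation between genes. MYC, a member that did not pass, differed by -0.10 (adjusted p = 0.549).

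**Figure D2:**
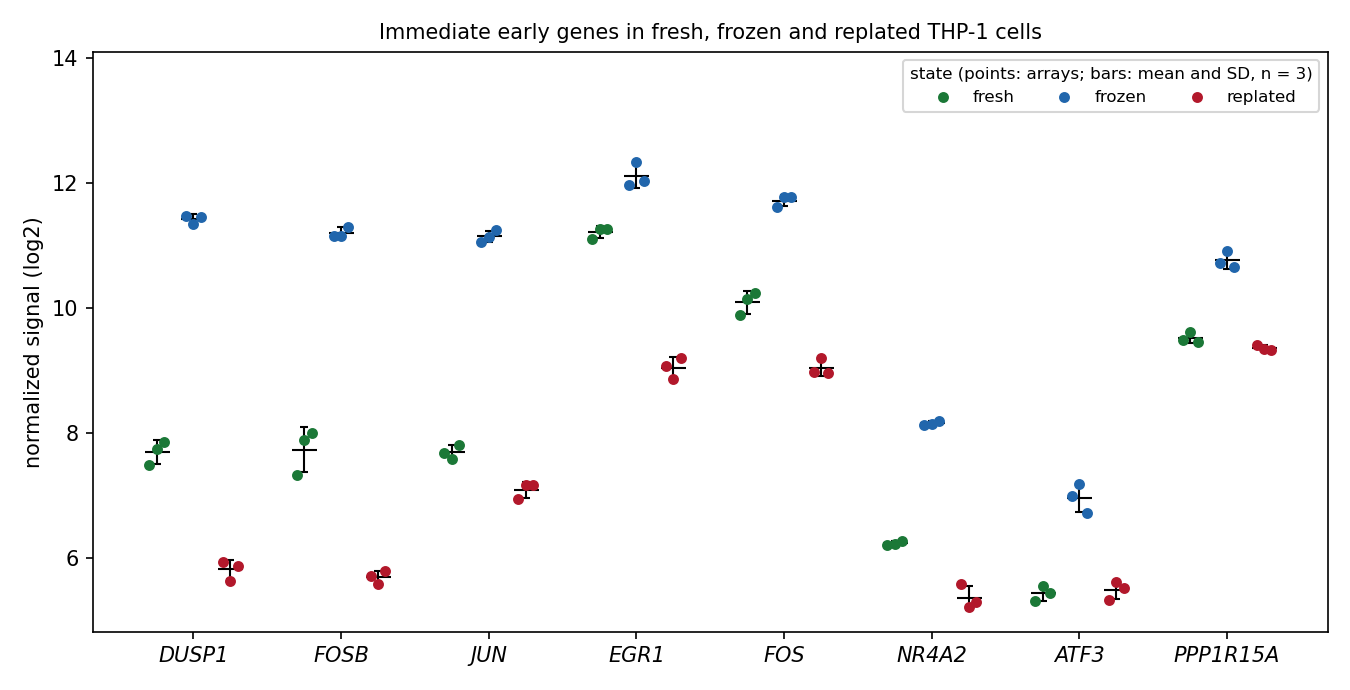
Normalized log2 signal (vertical axis) of 8 immediate early genes on each array, with points for arrays, colours for states and black bars for the mean and SD of 3 arrays. DUSP1 averaged 7.69 in fresh, 11.42 in frozen and 5.82 in replated cells, and JUN averaged 7.69, 11.14 and 7.09.

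Outside that list, 3 of the 18 tested NF-kB and inflammatory genes rose in frozen cells and 0 fell (4 rose when adjusted over the list alone). They were PTGS2, which encodes the prostaglandin-forming enzyme cyclooxygenase-2 (2.16-fold, adjusted p = 0.00237), the chemokine gene CCL3 (2.00-fold, adjusted p = 0.0244) and NFKBIZ, which encodes a nuclear regulator of NF-kB (1.34-fold, adjusted p = 0.045). The other probe of PTGS2 differed by 0.16 (adjusted p = 0.652). The list had a median log2 difference of 0.12 and a camera adjusted p of 0.00627, which became adjusted p = 0.229 with an estimated correlation; with no filter on dim probes its adjusted p was 0.0849. RPPH1, the RNA subunit of ribonuclease P, rose 2.42-fold (1.27 ± 0.079, adjusted p = 2.24e-05) and RNU11, an RNA of the minor spliceosome, rose 2.23-fold (1.16 ± 0.10, adjusted p = 0.000316). Whether probes of small RNAs, here and below, read the mature RNA or longer transcripts that hold its sequence was not tested. ACTA1, skeletal muscle actin, was not detected on any fresh array and was at least 2.10-fold higher in frozen cells (adjusted p = 0.0212), although its probe may bind transcripts of other actins. Among monocyte and macrophage markers, APOE rose 1.26-fold (adjusted p = 0.0497) and CCR2, a chemokine receptor, fell 1.46-fold (adjusted p = 0.00432), while 22 of 24 did not pass (2 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.539). The other probe of CCR2 differed by -0.165 (adjusted p = 0.346). The histone gene H2AC20 rose 1.32-fold (adjusted p = 0.0295), as 1 of 9 histone genes tested (2 when adjusted over the list alone; camera adjusted p = 0.757); histone probes may bind related copies.

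Decreases in frozen cells were smaller, and no called gene was 2-fold lower against 12 that were at least 2-fold higher. The small nucleolar RNA SNORD14A fell 1.90-fold (-0.93 ± 0.11, adjusted p = 0.0036) and SNORD14D fell 1.68-fold (-0.75 ± 0.13, adjusted p = 0.0227); the copies SNORD14B (-0.31) and SNORD14C (0.19), looked at after the values were seen, did not pass, and probes of this family may bind more than 1 copy. TAF1D, a subunit of the RNA polymerase I initiation factor, fell 1.82-fold (adjusted p = 0.0151), and its other probe differed by 0.04. The microRNA host transcript MIR181A2HG fell 1.68-fold, the deubiquitinase gene USP12 fell 1.65-fold, HNRNPA3, an RNA-binding protein gene, fell 1.64-fold and the syndecan gene SDC2 fell 1.58-fold, with adjusted p between 0.0195 and 0.0287. POFUT1, an O-fucosyltransferase gene, fell 1.52-fold on 1 probe and differed by 0.03 on the other, and HDHD2 fell 1.51-fold. DDIT4, an mTORC1 inhibitor gene, fell 1.52-fold (adjusted p = 0.0142) and ATF3 rose, so that 20 of 22 amino acid and integrated stress response genes did not pass (1 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.967). RPS15 fell 1.28-fold (adjusted p = 0.0377), as 1 of 33 cytosolic ribosomal protein genes (2 when adjusted over the list alone; camera adjusted p = 0.534); its other 2 probes differed by -0.05 and 0.16. Of the genes fixed beforehand, FOS rose, as given above, and the others tested did not pass. CIRBP, a cold-inducible RNA-binding protein, differed by -0.09 ± 0.084, GAPDH by 0.01 ± 0.067, CD14 by 0.24 ± 0.072 and ACTB by -0.18 ± 0.070. ACTB lay at 0.10 after median centring, and its lowest limma adjusted p over the alternatives was 0.0342.

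In total 184 of 18102 probes were called between frozen and fresh cells, 88 higher and 96 lower, and 3115 had an unadjusted p under 0.05. By the brightest kept probe of each gene, 104 of 10919 genes were called, 51 higher and 53 lower. A further 45 called probes had no gene name. The split of probes depended on the scaling, with 200 higher and 87 lower after median centring, 199 and 386 with normexp at offset 50, and 188 and 374 with no background correction. The count of called probes also fell whichever array was left out, to between 52 and 139, where fewer arrays remain. It was 73, 52 and 76 without fresh replicates 1, 2 and 3, 92, 57 and 102 without frozen replicates 1, 2 and 3, and 119 without replated replicate 2. Of the 27 called genes or list members that the naming rule gave, 15 lost their call when 1 array or another was left out. DUSP1, FOSB, JUN, NR4A2, FOS, ATF3, RPPH1, PPP1R15A, RNU11, SNORD14A, PTGS2 and CCR2 passed at an adjusted p under 0.05 wherever they were tested again except, for 9 of them, in a test of each probe with no pooled spread. Stricter thresholds were applied to counts only. DUSP1, FOSB, NR4A2, ATF3 and RPPH1 had no value under the filter that required a stricter detection p, under 0.01, on all 9 arrays.

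Replated cells had lower transcripts of 12 of 26 immediate early genes than fresh cells (camera adjusted p = 0.0527 for the list with an estimated correlation). They had higher transcripts of 7 of 24 monocyte and macrophage markers. GPNMB, a transmembrane glycoprotein of macrophages, rose 3.53-fold (1.82 ± 0.10, adjusted p = 1.27e-05). The cholesterol exporter ABCA1 rose 2.17-fold (1.12 ± 0.11), the lysosomal thiol reductase IFI30 rose 2.09-fold (1.07 ± 0.14) and lysozyme, LYZ, rose 1.80-fold (0.85 ± 0.064). The scaffold genes AHNAK2 and AHNAK rose 2.35-fold and 1.86-fold, the intermediate filament gene VIM rose 2.00-fold, and S100A10 rose 1.71-fold. GBP2, an interferon-inducible GTPase gene, rose 1.79-fold and EPAS1, which encodes HIF-2 alpha, rose 1.77-fold. Adjusted p for these 10 genes lay between 1.27e-05 and 0.00313.

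Among 24 monocyte and macrophage markers, 7 rose, 0 fell and 17 did not pass (9 rose when adjusted over the list alone), with a median log2 difference of 0.12 and a camera adjusted p of 3.8e-05, or adjusted p = 0.0433 with an estimated correlation. Besides GPNMB and LYZ they included CYBB, the catalytic subunit of the phagocyte NADPH oxidase (1.55-fold), and S100A8, a calcium-binding protein of myeloid cells (1.34-fold); CD14 differed by 0.10 ± 0.072 and did not pass. Of 6 MHC class II genes, HLA-DRA (1.32-fold), HLA-DRB1 (1.25-fold) and HLA-DMA (1.23-fold) rose and 3 did not pass (4 rose when adjusted over the list alone; median 0.31, camera adjusted p = 0.000731, adjusted p = 0.0547 with an estimated correlation); HLA probes may bind more than 1 HLA gene. Of 8 fatty acid synthesis genes, 3 rose (4 when adjusted over the list alone): the regulator SREBF1 (1.70-fold), the desaturase SCD (1.45-fold) and ACSS2 (1.21-fold), with a list median of 0.20 and a camera adjusted p of 0.000313, or adjusted p = 0.0845 with an estimated correlation. Of 18 cholesterol genes, INSIG1 (1.58-fold), MSMO1 (1.42-fold) and LSS (1.32-fold) rose and 15 did not pass (4 rose when adjusted over the list alone; median 0.13, camera adjusted p = 0.00196, adjusted p = 0.266 with an estimated correlation). The other LSS probe differed by -0.03.

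The largest decreases in replated cells were again in immediate early genes. EGR1, a zinc finger transcription factor, fell 4.49-fold (-2.17 ± 0.11, adjusted p = 7.54e-06), FOSB fell 4.11-fold (-2.04 ± 0.15), DUSP1 fell 3.67-fold (-1.88 ± 0.11) and FOS fell 2.06-fold (-1.04 ± 0.10). CCN1, a secreted matricellular protein gene, was not detected on any replated array and was at least 1.78-fold lower (adjusted p = 0.00159). Of 26 immediate early genes, 12 fell and 0 rose (17 fell when adjusted over the list alone), with a median of -0.37 and a camera adjusted p of 1.54e-12, or adjusted p = 0.0527 with an estimated correlation. The inhibitors of differentiation ID1 and ID3, which block basic helix-loop-helix factors, fell 3.58-fold (-1.84 ± 0.082) and 2.80-fold (-1.49 ± 0.065), both with an adjusted p of 2.27e-06. The homeobox gene DLX3 fell 2.13-fold, CD1D, which presents lipid antigens, fell 2.00-fold, and the cytokine receptor gene IL21R fell 2.08-fold on 1 probe and differed by 0.11 on the other.

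Of 19 unfolded protein response genes, 6 fell in replated against fresh cells, including the endoplasmic reticulum chaperone HYOU1 (1.42-fold), DNAJC3 (1.38-fold) and SDF2L1 (1.33-fold), and 13 did not pass (8 fell when adjusted over the list alone; median -0.17, camera adjusted p = 5.73e-05, adjusted p = 0.0433 with an estimated correlation). Of 22 ribosome biogenesis genes, NOLC1 (1.27-fold) and NIP7 (1.19-fold) fell (7 when adjusted over the list alone; median -0.18, camera adjusted p = 9.89e-05, adjusted p = 0.0527 with an estimated correlation). Of 24 G1 and S phase genes, RRM2, a ribonucleotide reductase subunit (1.35-fold), and MCM3, part of the replicative helicase (1.24-fold), fell (3 when adjusted over the list alone; median -0.11, camera adjusted p = 0.000966, adjusted p = 0.0527 with an estimated correlation). The 26 G2 and M phase genes had a median of 0.09 and a camera adjusted p of 0.0685. Of 6 metallothionein genes, MT1G (1.36-fold) and MT1H (1.29-fold) fell (3 when adjusted over the list alone; median -0.17, camera adjusted p = 0.00161, adjusted p = 0.13 with an estimated correlation), and probes of this family may bind several of its genes. CIRBP fell 1.48-fold (-0.56 ± 0.084, adjusted p = 0.00628), as the member that changed among 3 cold-inducible genes tested (1 when adjusted over the list alone; camera adjusted p = 0.269).

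Some lists without a called test held 1 to 4 changed members in replated against fresh cells. TNF (1.65-fold lower, adjusted p = 0.028) and NFKBIA, the inhibitor of NF-kB (1.41-fold lower, adjusted p = 0.0111), fell among 18 NF-kB and inflammatory genes (2 when adjusted over the list alone, where 2 others rose; camera adjusted p = 0.438). The pro-apoptotic gene PMAIP1 fell 1.73-fold (adjusted p = 0.00995), as the member of 16 apoptosis regulators that changed (3 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.757). DDIT4 rose 1.43-fold and MTHFD2 1.25-fold, while the amino acid transporter gene SLC7A5 fell 1.35-fold and ASNS 1.24-fold, out of 22 amino acid and integrated stress response genes (2 rose and 6 fell when adjusted over the list alone; camera adjusted p = 0.091). The other ASNS probe differed by -0.005 (adjusted p = 0.987). The myosin light chain gene MYL9 rose 1.56-fold and CNN3 fell 1.25-fold among 18 actin and SRF genes (3 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.187). The other MYL9 probe differed by 0.16 (adjusted p = 0.509). CD79B, a B cell receptor subunit in the list of markers of other cell types, rose by 0.37 on the log2 scale, and the other 3 markers tested, CD79A, MS4A1 and PECAM1, did not pass (1 rose when adjusted over the list alone; camera adjusted p = 0.473). Among 14 p53 targets CCNG1 rose 1.34-fold and AEN fell 1.36-fold (2 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.97). Among 23 interferon response genes IFI6 rose 1.28-fold and IFIT2 fell 1.36-fold (3 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.757). The quinone reductase gene NQO1 rose 1.23-fold among 14 NRF2 genes (1 when adjusted over the list alone; camera adjusted p = 0.757). The glycolytic genes ALDOC (1.47-fold) and PFKFB4 (1.26-fold) rose among 16 hypoxia genes (2 when adjusted over the list alone; camera adjusted p = 0.304). The sialidase gene NEU1 rose 1.27-fold among 19 lysosome and autophagy genes (2 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.221). RPS7 fell 1.28-fold among 33 ribosomal protein genes (1 when adjusted over the list alone; camera adjusted p = 0.794). GAPDH differed by 0.11 ± 0.067, MYC by 0.16 ± 0.080 and ACTB by 0.02 ± 0.070 with no call.

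**Figure D3:**
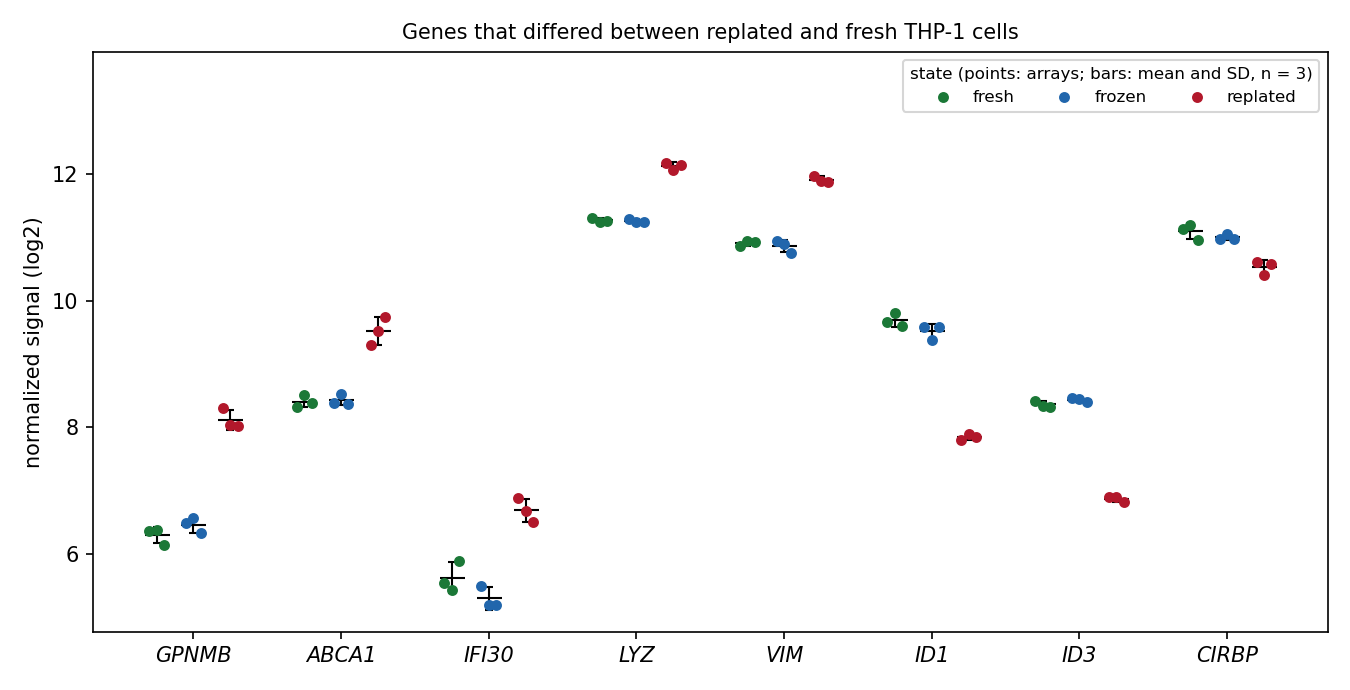
Normalized log2 signal (vertical axis) of 8 genes that differed between replated and fresh cells, with points for arrays, colours for states and black bars for the mean and SD of 3 arrays. ID1 lay between 7.80 and 7.89 on replated arrays and between 9.38 and 9.80 on fresh and frozen arrays, and LYZ lay between 12.05 and 12.17 on replated arrays and between 11.24 and 11.31 on the other arrays.

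Between replated and fresh cells, 747 of 18102 probes were called, 402 higher and 345 lower, and 3617 had an unadjusted p under 0.05. By the brightest kept probe of each gene, 501 of 10919 genes were called, 266 higher and 235 lower. Of these, 4 were at least 2-fold higher and 9 at least 2-fold lower. The count of called probes was 351, 276 and 406 without fresh replicates 1, 2 and 3, and 318, 326 and 245 without replated replicates 1, 2 and 3. Of 61 named calls, 31 were lost when 1 array or another was left out. Where the 20 genes with the largest changes were tested again at an adjusted p under 0.05, calls were lost only in the test with no pooled spread. Among them, 7 (AHNAK2, IFI30, GBP2, FOSB, DUSP1, IL21R and CCN1) had no value where a detection p under 0.01 on all 9 arrays was required.

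The direct comparison of replated with frozen cells gave the widest differences. DUSP1 was 48.8-fold lower in replated cells (-5.61 ± 0.11, adjusted p = 6.37e-10), FOSB 45.5-fold lower (-5.51 ± 0.15) and JUN 16.6-fold lower (-4.05 ± 0.091). The size depended on the processing. Over the alternatives the log2 difference ranged from -6.17 to -4.76 for DUSP1, -6.13 to -4.60 for FOSB and -4.25 to -3.65 for JUN. EGR1 fell 8.37-fold, NR4A2 6.90-fold, FOS 6.38-fold and TRIB1, a pseudokinase gene, 3.90-fold. CCN1 was at least 2.75-fold lower. Of 26 immediate early genes, 21 fell and 0 rose (23 fell and 1 rose when adjusted over the list alone), with a median of -0.90 and a camera adjusted p of 9.7e-26, or adjusted p = 0.0433 with an estimated correlation. Inflammatory genes fell in 5 of 18 cases, including CCL3 (2.70-fold, detected on 1 of 3 replated arrays), TNF (2.36-fold), PTGS2 (2.28-fold) and the chemokine gene CXCL8 (1.60-fold); 5 fell and 1 rose when adjusted over the list alone, and the median was -0.13 with a camera adjusted p of 0.0076, or adjusted p = 0.233 with an estimated correlation. RPPH1 was 3.01-fold lower and ID1 3.18-fold lower in replated cells.

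GPNMB (3.14-fold), IFI30 (2.62-fold), DDIT4 (2.17-fold), ABCA1 (2.13-fold), VIM (2.07-fold), AHNAK (2.01-fold), AHNAK2 (2.00-fold), GBP2 (2.00-fold) and CCR2 (1.96-fold) were higher in replated than in frozen cells, with adjusted p between 7.81e-06 and 0.00416. TAF1D was 2.22-fold higher on 1 probe and differed by 0.14 on the other. Of 24 monocyte and macrophage markers, 9 rose (10 when adjusted over the list alone; median 0.14, camera adjusted p = 9.1e-05, adjusted p = 0.0433 with an estimated correlation), among them LYZ (1.81-fold) and CYBB (1.62-fold). HLA-DRB1 (1.37-fold), CD74, the invariant chain (1.33-fold), and HLA-DRA (1.28-fold) rose among 6 MHC class II genes (4 when adjusted over the list alone; median 0.31, camera adjusted p = 0.00469, adjusted p = 0.0923 with an estimated correlation). SREBF1 (1.74-fold), SCD (log2 difference 0.58) and ACSS2 (1.23-fold) rose among 8 fatty acid synthesis genes (4 when adjusted over the list alone; median 0.20, camera adjusted p = 0.00185, adjusted p = 0.13 with an estimated correlation). MSMO1 (1.54-fold), INSIG1 (1.53-fold), LSS (1.35-fold, other probe -0.02) and SQLE (log2 difference 0.26) rose among 18 cholesterol genes (5 when adjusted over the list alone; median 0.11, camera adjusted p = 0.0446, adjusted p = 0.535 with an estimated correlation). That last call was lost without fresh replicate 2 (adjusted p = 0.0525), fresh replicate 3 (0.0579), replated replicate 3 (0.129) or frozen replicate 1 (0.151).

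In replated against frozen cells 8 of 19 unfolded protein response genes fell, such as MANF (1.43-fold), DNAJC3 (1.39-fold) and DNAJB11 (1.37-fold), with 11 lower and 2 higher when adjusted over the list alone (median -0.25, camera adjusted p = 0.000731, adjusted p = 0.0527 with an estimated correlation). NOLC1 (1.38-fold), MRTO4 (1.26-fold) and RRP12 (1.23-fold) were among 5 of 22 ribosome biogenesis genes that fell (9 when adjusted over the list alone; median -0.18, camera adjusted p = 0.000952, adjusted p = 0.0827 with an estimated correlation). CDC45 and MCM2 (both 1.24-fold) were among 4 of 24 G1 and S phase genes that fell (4 when adjusted over the list alone; median -0.14, camera adjusted p = 0.000966, adjusted p = 0.0527 with an estimated correlation). MT1G (1.32-fold), MT1X (1.28-fold) and MT2A (1.19-fold) fell among 6 metallothioneins (3 when adjusted over the list alone; median -0.19, camera adjusted p = 0.0259, adjusted p = 0.235 with an estimated correlation). Mitotic genes NEK2 (1.46-fold), BUB1B (1.40-fold), CCNB1 (1.34-fold) and DLGAP5 (1.24-fold) rose among 26 G2 and M phase genes (6 rose and 1 fell when adjusted over the list alone), while the list's camera adjusted p was 0.054.

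**Figure D4:**
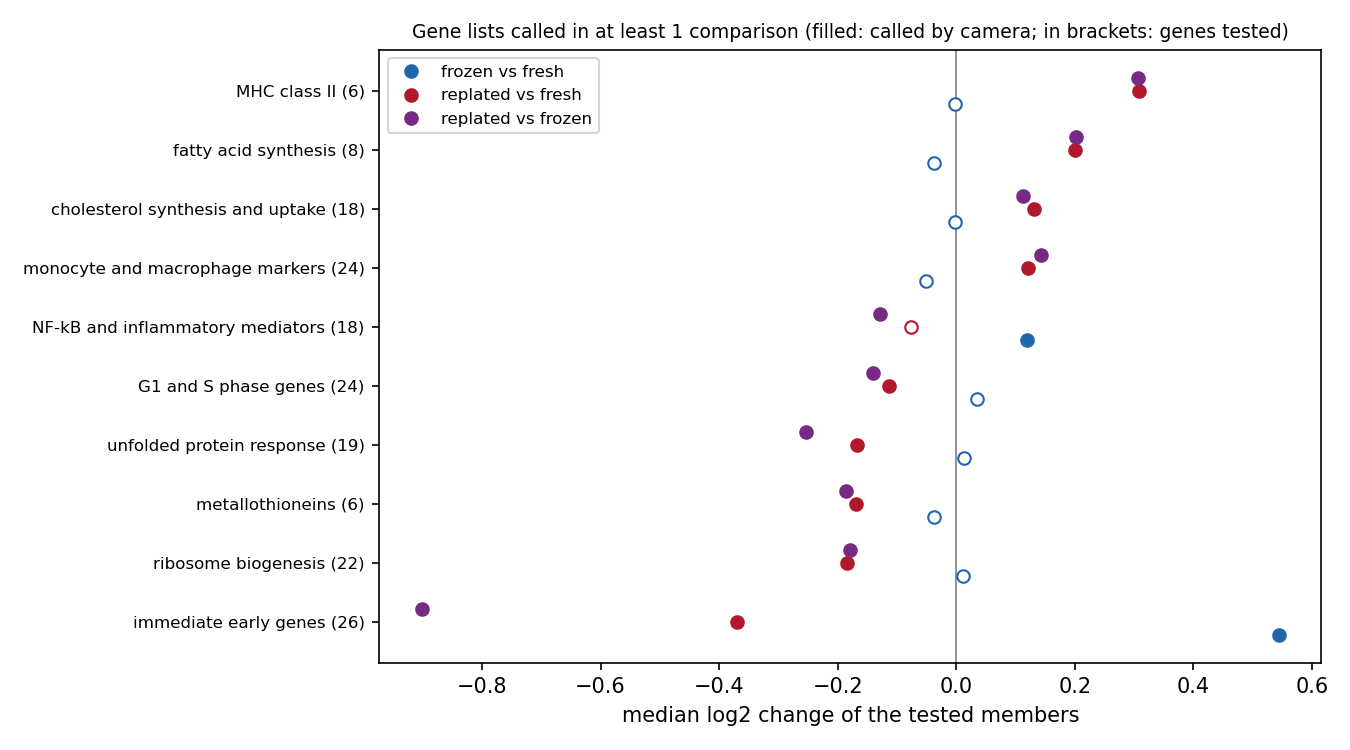
Median log2 difference (horizontal axis) of the tested members of 10 gene lists (vertical axis, number of genes tested in brackets) in 3 comparisons marked by colour, with filled points where camera called the list and open points elsewhere. Immediate early genes had medians of 0.54, -0.37 and -0.90 in frozen against fresh, replated against fresh and replated against frozen cells.

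The remaining lists were not called between replated and frozen cells, though some members changed. ATF3 (2.79-fold), SLC7A5 (1.45-fold) and SLC3A2 (1.36-fold) were among 7 amino acid and integrated stress response genes that fell while 2 rose out of 22 (8 fell and 5 rose when adjusted over the list alone; camera adjusted p = 0.132). The p53 targets CCNG1 (1.63-fold) and DDB2 (1.36-fold, detected on 1 of 3 frozen arrays) rose and AEN fell (1.28-fold) among 14 (3 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.728). H2AC18 (1.58-fold), H2AC20 (1.41-fold) and H1-2 (1.37-fold) fell among 9 histone genes (3 when adjusted over the list alone; camera adjusted p = 0.305). PMAIP1 (1.71-fold) and MCL1 (log2 difference -0.26) fell while CFLAR (1.38-fold) and BAK1 (1.38-fold) rose among 16 apoptosis regulators (2 fell and 3 rose when adjusted over the list alone; camera adjusted p = 0.898). SGK1 (1.72-fold) and GADD45B (1.37-fold, arrays overlapping) fell among 8 osmotic stress genes (2 fell and 2 rose when adjusted over the list alone; camera adjusted p = 0.794). TPM4 (1.40-fold) and MYL9 (1.35-fold) rose and CNN3 (1.25-fold) fell among 18 actin and SRF genes (2 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.339). RPL37 (log2 difference 0.58), RPL23 (1.29-fold) and RPS15 (1.19-fold) rose and RPS7 fell (1.48-fold) among 33 ribosomal protein genes (3 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.757). Another RPS15 probe fell by 0.32 on the log2 scale. CD79B (1.35-fold) and PECAM1 (log2 difference 0.26), markers of B cells and of endothelium, platelets and leukocytes, rose among 4 tested markers of other cell types (2 when adjusted over the list alone; camera adjusted p = 0.142).

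In each of 11 further lists at most 3 members passed between replated and frozen cells. STIP1, a co-chaperone gene, fell 1.18-fold among 18 heat shock genes (0 when adjusted over the list alone; median -0.02, camera adjusted p = 0.794). These had a median of -0.02 in frozen against fresh cells as well (camera adjusted p = 0.757). CIRBP fell 1.39-fold among 3 cold-inducible genes (1 when adjusted over the list alone; camera adjusted p = 0.438). IFIT2 fell 1.48-fold among 23 interferon response genes (1 when adjusted over the list alone; camera adjusted p = 0.539). SRXN1 (1.26-fold) and GCLM (1.22-fold) fell and TKT (log2 difference 0.27) rose among 14 NRF2 genes (2 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.645). HK2 fell by 0.26 on the log2 scale on 1 probe and rose on another (0.41, adjusted p = 0.0388) among 16 glycolysis genes (0 when adjusted over the list alone; camera adjusted p = 0.967). ALDOC rose 1.21-fold and AK4 fell 1.21-fold among 16 hypoxia genes (2 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.539), with other AK4 probes at 0.28, 0.09 and -0.25. NDUFB5 fell by 0.26 on the log2 scale among 25 oxidative phosphorylation genes (0 when adjusted over the list alone; camera adjusted p = 0.584). GABARAPL1 fell 1.36-fold among 19 lysosome and autophagy genes (1 fell and 2 rose when adjusted over the list alone; camera adjusted p = 0.426). None of 10 immature myeloid markers (0 when adjusted over the list alone; camera adjusted p = 0.539) and none of 3 snoRNA host and nuclear non-coding RNAs (0 when adjusted over the list alone; camera adjusted p = 0.958) passed. B2M rose 1.19-fold among 14 reference genes (0 when adjusted over the list alone; camera adjusted p = 0.549). The brightest probes of ACTB (0.20), GAPDH (0.09), CD14 (-0.14) and MYC (0.27) did not pass, with ACTB at -0.11 after median centring. Other probes, looked at after the values were seen, did pass for ACTB (0.33, adjusted p = 0.0122), GAPDH (0.29, adjusted p = 0.0308) and MYC (0.71, adjusted p = 0.00188).

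Between replated and frozen cells, 2095 of 18102 probes were called, 1132 higher and 963 lower in replated cells, with 918 higher and 1479 lower after median centring, and 5236 had an unadjusted p under 0.05. By the brightest kept probe of each gene, 1322 of 10919 genes were called, 721 higher and 601 lower. Of these, 9 were at least 2-fold higher and 28 at least 2-fold lower. The count of called probes was 1282, 1321 and 1011 without replated replicates 1, 2 and 3, and 1160 and 1225 without frozen replicates 2 and 3.

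Genes such as DUSP1, FOSB, JUN, EGR1, FOS, NR4A2, KLF2, CCN1 and TRIB1 were higher in frozen and lower in replated than in fresh cells, 12 genes in all. CCR2, DDIT4 and TXNIP went the other way. ABHD15, CTSF and GPR183 were higher in both states. CD1D, DNAJC2, HNRNPA3, MRC2, RANBP9, SNORD14A and SNORD30 were lower in both. In probes, 16 were called in the same direction in both comparisons with fresh cells (7 higher, 9 lower) and 19 in opposite directions, where independent lists would share 1.95 higher, 1.83 lower and 3.81 opposite. Both comparisons use the same fresh arrays, and 100 simulations of unchanged groups against those arrays gave at most 0 shared calls. Since the simulated groups held no change, that 0 does not show what the shared fresh arrays add where calls exist. With 3 fresh arrays the controls could not be divided, so part of the excess may come from sharing them. Across probes, which are not independent replicates, the log2 differences correlated at 0.136 against a simulated mean of 0.501 (0.483 to 0.514). Their covariance was 0.00425 against a simulated 0.00521 (0.00495 to 0.00548), a difference of -0.00096. The number of shared calls fell to 5, 3 and 7 without fresh replicates 1, 2 and 3, 6 and 5 without frozen replicates 1 and 2, and 6, 5 and 5 without replated replicates 1, 2 and 3.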

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

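The test of the immediate early gene list without DUSP1, FOSB, JUN and NR4A2 was chosen after seeing the data; the other alternatives were set beforehand. Counts are given in the order frozen against fresh, replated against fresh, replated against frozen, the F test and calls shared by both comparisons with fresh, where main values were 184, 747, 2095, 1743 and 16. An offset of 50 gave 585, 1359, 2978 (F test) and 57 (shared), no background correction 562, 1303, 2871 (F test) and 55 (shared), and median centring 287 in the first. The authors' values gave 103, 427, 1062 (F test) and 8 (shared). Probes detected on all 9 arrays, at a detection p under 0.01 rather than 0.05, gave 366, 1199 and 49 (shared). Only the 2 states compared gave 54 in the first and 5 shared, a trend and robust prior 826, 1526, 3266, 3426 and 84, and a plain t-test without pooling 6, 86, 440 and 0 shared (limma's unadjusted p under 0.05 held for 3115 and 3617 probes). An adjusted p under 0.01 gave 40, 164, 613, 408 and 2, and a fold of at least 1.5 gave 65, 116, 292, 336 and 2, by construction fewer. Apart from these and the smaller number of arrays, the cause was not tested. With 1 array left out the counts ranged from 52 to 139, 245 to 696, 1011 to 2028, 712 to 1428 and 3 to 13, and called list tests from 20 to 23.

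Of 90 list tests 21 were called, 5 with an estimated correlation, 37 with fry's directional and 72 with fry's mixed test, which do not compare a list with other genes. Without its 4 largest members the immediate early list stayed called (adjusted p 3.23e-15, 1.63e-07 and 2.24e-17). Other settings ended only 2 list calls, NF-kB in frozen against fresh cells with no filter (adjusted p 0.0849) and cholesterol in replated against frozen cells with only the 2 states (0.0601), the mean of all probes (0.0987) or 1 of 4 arrays left out (0.0525 to 0.151). Same-numbered arrays did not deviate together (correlations from -0.048 to 0.047), so no pairing was visible. Whether equal numbers mark a shared culture or day is not known. With the replicate number as a block the counts were 104, 444 and 6 (shared), and no list call changed. A block by chip was not run, since the files name no chip.

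Of 179 called gene and contrast pairs named, 0 turned direction and 47 kept their call at an adjusted p under 0.05 under every alternative that tested them, with 676 of the single calls lost and 2868 kept. Stricter thresholds were applied to counts only. Genes without a detection p under 0.01 on all 9 arrays had no value under the filter that required it. Direction turned only in pairs that were not called: ACTB was 0.103, -0.004 and -0.107 after median centring and, with 1 array left out, -0.0158 (without replated replicate 3) to 0.0481 in replated against fresh cells, and GAPDH, frozen vs fresh, ranged from -0.0021 (without frozen replicate 2) to 0.0375, with -5e-04 without fresh replicate 3. Mean background of 55.3 to 62.6 intensity units against median signals of 59.4 to 67.4 left most probes near background, where changes are understated.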

Other observations

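The tests of the fresh cells standing apart, of cycling cells and of snoRNA host genes were chosen after the results were seen. The first was changed more than once after that: list calls at the preset correlation (5 of 5 between replated and frozen cells) argued against the explanation, calls with an estimated correlation (1 of 5) left it open, and intervals over arrays replaced both. The test of cycling cells was likewise changed from a list call, which left it open, to such an interval, and the host test was afterwards limited to snoRNAs with a tested host. Small nucleolar RNAs, which guide chemical modification of other RNAs, and related small RNAs were not part of a fixed list and were looked at after the values were seen. Of 36 small nucleolar RNAs tested, 10 fell and 0 rose in replated against fresh cells, with a median log2 difference of -0.26 and negative values for 31. These are probe signals, which may come from the mature small RNAs or from longer transcripts that hold their sequence. SNORD35A fell 1.63-fold (adjusted p = 0.0324), SNORD30 1.59-fold (0.00375), SNORA70 1.43-fold (0.0132) and SNORD15B 1.41-fold (0.0177) by limma. In frozen against fresh cells the median was -0.12 with negative values for 24, and 3 rose, SNORD21 (1.54-fold), SNORD68 (log2 difference 0.58) and SNORD25 (1.42-fold), and 3 fell. In replated against frozen cells the median was -0.08 with negative values for 20, and 2 rose and 10 fell. The small Cajal body RNA SCARNA9 rose 1.69-fold in frozen cells (adjusted p = 0.000291), and SNAR-A1 fell 1.39-fold (adjusted p = 0.0195), though its family has several copies.

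Immediate early genes were higher in frozen and lower in replated than in fresh cells, the first with an adjusted p = 0.0433 with an estimated correlation and the second not called at that setting (adjusted p = 0.0527 with an estimated correlation). Other background corrections and normalizations argue against processing as the cause (largest camera adjusted p 5.31e-11, preset correlation). Leaving out each array in turn argues against a single array as the cause (largest camera adjusted p 6.92e-12, preset correlation). In frozen against fresh cells, 10000 signal-matched random lists had medians from -0.114 to 0.128. The share as large was 1e-04, the smallest they can give, which argues against a shift shared by genes of like signal. Whole-array brightness itself was not tested by these lists, since quantile normalization removes it beforehand, and replated cells were not covered. A processing day, chip or extraction batch that differs between states stays open, since 0 arrays have a label for it. No biological explanation was tested.

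Monocyte, macrophage and MHC class II genes were higher, and ribosome biogenesis, unfolded protein response and G1 and S phase genes lower, in replated than in fresh cells by camera at the preset correlation. With an estimated correlation the monocyte and unfolded protein response lists stayed called (adjusted p = 0.0433 each) and MHC class II (0.0547), ribosome biogenesis (0.0527) and G1 and S phase genes (0.0527) did not. Other normalizations argue against processing (largest camera adjusted p 0.000882, preset correlation). The fresh cells standing apart from both other states would put replated and frozen cells level. In 5 of 5 lists the 95% interval of replated minus frozen excluded 0 on the side of the change against fresh cells. It came from the spread between arrays of the list's mean log2 value. G1 and S phase genes lay at -0.14 (from -0.17 to -0.11) and MHC class II at 0.28 (from 0.18 to 0.37). Camera with an estimated correlation called only 1 of the 5 lists between replated and frozen cells. The lists were picked for their change in replated against fresh cells, and both comparisons use the same replated arrays. The intervals are therefore no independent test of this explanation. A lower share of cycling cells would lower G2 and M phase genes too. Their mean was 0.08 higher in replated than in fresh cells (95% interval over arrays from 0.0372 to 0.129). However, 0 of 26 rose or fell, and camera did not call the list (direction up, adjusted p 0.0685, or 0.229 with an estimated correlation). The interval leaves out the spread between genes and was chosen after the result was seen, so a lower share of cycling cells stays open. A batch (0 arrays labelled for a day or chip) also stays open, and no biological explanation was tested.

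For the lower small nucleolar RNAs, the highest median over other value sets was -0.164, which argues against normalization. The share of signal-matched random lists as low was 1e-04, the smallest they can give (medians from -0.124 to 0.145). The set was taken up after its values were seen, so this share and the permutation p below do not measure chance. Whole-array brightness was not tested by these lists, since quantile normalization removes it beforehand. For the 23 with 1 tested host gene, lower host transcripts are argued against: the hosts had a median of 0.009 with 0 of 15 called lower, and the median of snoRNA minus host was -0.346, negative for 18 of 23 (two-sided sign-flip permutation p = 0.00197, 1 value per host). The other 13 stay open, and with 63.9% covered (80% needed) the check is void for all 36 as a set. No biological explanation was tested.

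Other groupings of the arrays were compared with the real one. The 10 splits of 6 arrays are too few for a share under 0.05; in fits of those 6 arrays the real split called 54, 539 and 1691 probes, as did 1 of 10 in each case, and the highest other called 0. For the F test, 1 of 100 regroupings called as many as the real 1743 (highest other 378). That 1 was the real grouping itself, so the share is the smallest that 100 regroupings can give. Chance is therefore an unlikely source, but a batch that follows the states is not told apart by it. For shared calls 1 of 100 reached the real 16, but all 99 others gave 0 (highest other 0). Each regrouping also used its arrays relabelled as fresh in both comparisons. However, only 6 of the 99 others had any call in the F test, so there was little to share. This count therefore adds nothing on whether the overlap exceeds what the shared fresh arrays give. For list tests 2 of 100 reached the real 21, the real grouping included (highest other 22), but 87 of the 99 others called at least 1 pair, with a median of 6, so list calls at the preset correlation were common under other groupings, which keep part of the differences between states.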
